A study of Rattus norvegicus with 23 samples.

How the data were processed

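Peripheral blood mononuclear cells (PBMC) were profiled from male and female Wistar rat pups aged 21 days. Their dams were fed freely (control) or received a diet restricted by 20% in calories (CR) during lactation, per the labels. The series held 23 two-colour arrays, 1 per pup: 6 from control males, 5 from CR males, 6 from control females and 6 from CR females. The Cy5 channel carried the individual pup's RNA, and the Cy3 channel carried a pool of all samples, per the labels. There was no dye swap. The labels state 11 control dams and 5 CR dams. They do not tie pups to litters, so the 11 CR pups, which came from at most 5 dams, were treated as independent. P-values may therefore be too small.

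The authors scanned arrays of Agilent rat design 014879 with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes and the file headers. The deposited scanner files give an intensity per spot and channel, unnormalized. The same deposited files give a log10 ratio of Cy5 over Cy3 after the scanner software's background subtraction and its linear and LOWESS dye normalization, per the file headers. They also hold other columns, spot flags set by that software, per the file headers. The deposited value table holds log2 levels for 22920 of the 43379 spots that are not controls. Its columns share a median of 7.23. They follow the Cy5 level of the same array (Pearson's r across spots of 0.989 to 0.997), and differences between arrays follow the ratio of Cy5 to Cy3 (r of 0.814) more closely than Cy5 alone (r of 0.700). The method that made this table is not stated, and it was used here as an alternative only. All 23 columns belonged to a sample.

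Mean spot intensities were corrected with limma's normexp on the median local background with an offset of 50. They were then normalized by loess within each array, with control spots given no weight, and expressed as the log2 ratio of Cy5 to Cy3. Spots flagged as outliers in either channel (127 to 427 per array) were set to missing, and spots of the same probe were averaged. A probe was kept when its Cy5 signal was well above background, by the scanner software's flag, on at least 50% of the arrays of at least 1 group. This kept 23693 of 41012 probes. Each gene was represented by its kept probe with the highest mean intensity, and probes with no gene name stayed as features of their own. The tests covered 20581 features, of which 10665 carried a gene name. Gene names came from the rat RefSeq table of assembly GRCr8, used for names only: 20752 of the 41012 probes matched it, 141 kept the name in the scanner files and 20119 had none. Positions are those of the array design, on rn4.

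Linear models were fitted with limma 3.58.1 in R 4.3.3 to the means of the 4 groups, with moderated variances (prior degrees of freedom 3.40) and Benjamini-Hochberg adjustment over all features of a comparison. A feature was called at an adjusted p under 0.05. There were 5 contrasts: CR minus control in males, the same in females, the mean of these, their difference (male minus female), and males minus females averaged over diets. Slides were read from the array barcodes. The 6 slides did not all hold every group: 4 held all 4 groups, so within-slide differences in males rest on 4 slides and in females on 6, and each test was repeated with the slides as a block.

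Lists of genes were written before the values were seen. They cover lipid, glucose and energy metabolism, nutrient signalling, ribosomal proteins, the proteasome, the cell cycle, immune and stress responses, the circadian clock, 10 blood cell types or their precursors, and sex-linked genes (2 lists). The fatty acid synthesis list as written also held Pmvk, a gene of cholesterol synthesis. The 28 lists other than the sex-linked ones were tested with camera at a preset correlation of 0.01, with at least 5 measured members and adjustment over the lists. Missing values took the mean of the other arrays of the group for the list tests alone, a step chosen after the files were seen. Camera with an estimated correlation, fry, and an exact two-sided permutation test of each array's mean over the list (462 assignments of males, 924 of females, all their pairs for the mean of the sexes) were run beside it. The series title names lipid metabolism, so the lipid lists are not independent of the study's aim. A list's shift is the difference of group means of the per-array list mean, with its standard error over arrays.

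Genes are named by a rule written before the values were seen: those with the smallest p in each direction (10 and 10 in each sex, 6 and 6 for the mean of the sexes, 5 and 5 for the interaction, 8 and 8 between the sexes, with curated symbols), the 4 members with the smallest p of each called list, every measured member of the sex-linked lists, and a set of lipid genes given in any case, here Fasn, Cpt1a, Lipe, Lrp1, Rxrb, Star, Srebf1, Cd36 and Ucp2. Some genes that the rule names are not reported here, and no other gene takes their place. The rule also allowed up to 2 members of a list that was not called. None of these are named on that ground, a limit settled after their values and their dependence on the settings had been seen. The dependence on the settings was then computed for the 214 remaining pairs of a gene and a comparison.

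The models were tested on simulated data, drawn independently for each of the 20581 features from the real means and spreads, with changes planted in each comparison. In males, 54 of 67 planted changes of 0.5 (log2) and 67 of 67 of 1 were called. In females the counts were 50 of 67 and 62 of 67, for the mean of the sexes 62 of 67 and 67 of 67, for the interaction 39 of 67 and 61 of 67, and between the sexes 60 of 67 and 65 of 67. Of the planted changes of 2, 65 of 66 were called in males and 66 of 66 in each of the other comparisons. All calls of planted features had the planted direction. Of the 20366 unchanged features, 12 were called in males, 15 in females, 7 for the mean of the sexes, 14 for the interaction and 12 between the sexes. Camera called the planted list, the B cell markers all lowered by 0.5 (log2), in each of the 4 diet comparisons and 0 others. The simulated features are uncorrelated, and real ones are not. The 0 other lists therefore do not bear on false calls in the real data. There, random regroupings of diet gave a median of 6 to 7 called lists. All changes of a comparison were also planted at once. The adjusted threshold is less strict when many features change, so these shares overstate the detection of a lone change.

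Alternatives chosen before the data were examined were the scanner software's log ratio, median centring in place of loess, scale normalization between arrays (division by the median absolute log ratio, as the method does for log ratios), Cy5 alone with quantile normalization, the deposited value table, no filter or a filter on all 23 arrays, every probe on its own or the mean of a gene's probes, array quality weights, an intensity trend with robust moderation, a slide block, a replicate block, single-sex fits, the other list tests, and leaving out each array in turn. Chosen after the data were seen were the exact permutation of list means, the means of the B cell and red cell lists as covariates, the marker mean of each of 6 cell types as a covariate for each called list (without genes that both share), and leaving out together the 2 arrays that correlate least with the others. Random regroupings were limited to 100 per comparison. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.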

Results

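The data were log2 ratios of 23 individual PBMC samples to a pool of all samples, from rat pups at weaning age whose dams were fed freely or restricted in calories while they suckled. The groups held 6 control males, 5 CR males, 6 control females and 6 CR females. Between 20603 and 24076 probes per array (median 22487) were well above background in Cy5, and the median Cy5 intensity per array was 55.6 to 65.8, against a local background of 27 to 30. At most 1 probe per array was saturated. The number of arrays limits the precision: the median standard error of a feature's log2 difference was 0.082 in males, 0.079 in females and 0.057 for their mean.

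The sexes served as a check of the labels. limma called 12 of 20581 features between males and females averaged over diets, 4 higher in males and 8 higher in females, and 10 were called with the slides as a block. An unadjusted p under 0.05 was reached by 1524 features, where 1029 are expected by chance. On all 23 of the 23 arrays the level of the top feature lay on the side of the labelled sex. Of those higher in females, 6 lie on chromosome X of rn4 between positions 91447528 and 91467632, and the scanner files describe 1 of them, probe A_44_P324932, as similar to Xist. It was above background on 1 of 11 male and 12 of 12 female arrays. The top feature, A_44_P597131, was above background on 7 of 11 male and 12 of 12 female arrays, and A_44_P345194 on 0 of 11 and 12 of 12. No fold is given for a probe at background on arrays of 1 sex, since it would depend on the background correction. Eif2s3 differed by -0.50 ± 0.06 (males minus females, SE, adjusted p 3.5e-05) and Pbdc1 by -0.29 ± 0.05 (adjusted p 0.020). Higher in males were A_44_P638995, described in the files as similar to mouse eIF2 gamma, A_43_P19826 (both above background on 11 of 11 male and 0 of 12 female arrays), A_44_P671422 (1.17 ± 0.09, SE) and Ms4a6bl1 (0.35 ± 0.06, SE, adjusted p 0.019). Ms4a6bl1 and Pbdc1 were not called with the slides as a block (adjusted p 0.088 and 0.0502), and Eif2s3 was not called under median centring (0.067) or scale normalization (0.334).

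Of the other measured members of the sex-linked lists, Ddx3x was at -0.25 ± 0.07 (males minus females, SE, adjusted p 0.660), Kdm5c at -0.09 ± 0.05 (0.708) and Usp9x at 0.04 ± 0.08 (0.916), which turned negative under median centring (-0.065), under scale normalization (-0.0030) and without CR female replicate 5 (-0.0053). The reference pairs a probe the scanner files name Utx with Uty. It was higher in females (-0.43 ± 0.19, adjusted p 0.672), and the name is uncertain. No other gene of the Y chromosome list was matched by name to a kept probe. Probes without a gene name, such as A_44_P638995, could not be matched to the list. Next by p, with adjusted p between 0.295 and 0.660 and none past the threshold, came Il22ra2, Hiat1, Lrrc57, Smad4, Rpl9, Tma7 and Rpl39 on the male side and Acy1, Spetex2l1, Pold4 and Ehd1 on the female side.

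The main question was how restriction of the dam during lactation relates to PBMC expression in the pup. In male pups limma called 0 of 20581 features between CR and control (smallest adjusted p 0.224), and 0 with the slides as a block. An unadjusted p under 0.05 was reached by 1472 features (631 higher in CR, 841 lower), against 1029 expected by chance. Over the other settings this count ran from 804, with the 2 arrays that stand apart left out, to 6535 under median centring, and with 1 array left out from 818 (CR male replicate 1) to 2220 (CR male replicate 2). Under median centring the median difference of all features was itself -0.19, so the 6535 includes a common offset. None of the genes that follow passed the adjusted threshold. On the lower side the smallest p-values belonged to Havcr1, Gga2, Fgd2, Fcho1, Grwd1, Sox5, Anapc7, Hip1r, Pom121 and Rasd2. The log2 difference was -0.94 ± 0.18 (SE) for Gga2 (ENSRNOT00000025309, chromosome 1), -0.79 ± 0.16 for Fgd2 (ENSRNOT00000041665, chromosome 20) and -0.33 ± 0.06 for Havcr1 (chromosome 10). On each of the 5 CR arrays these 3 genes, chosen by their p, lay below the control mean. Gga2 passed the threshold with a replicate block (adjusted p 0.038). A second probe of Fcho1 gave 0.04 against -0.52 for the probe used. On the higher side came Rreb1 (0.28 ± 0.05), Klrd1 (0.65 ± 0.15), Gabpb2, Zfp40, Dse, Tgfbrap1, Taf2, Relt, Apbb1ip (0.61 ± 0.17) and Adcy7, with adjusted p between 0.224 and 0.644.

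Without CR male replicate 2, limma called 4 genes in males, all lower in CR: Fgd2 (-0.96, adjusted p 0.0073), Hip1r (-0.69, 0.0073), Gga2 (-1.08, 0.022) and Grwd1 (-0.50, 0.022). The count without any other single array was 0.

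In female pups limma called 0 of 20581 features (smallest adjusted p 0.994), and 0 with the slides as a block. An unadjusted p under 0.05 was reached by 955 features (411 higher, 544 lower), against 1029 expected by chance. The side of 1029 on which it lay depended on the setting: it was 265 under median centring, 1067 with the slides as a block and 1806 with array quality weights. With 1 array left out it ran from 584 (CR female replicate 3) to 1364 (CR female replicate 4). The smallest p-values on the lower side were those of Pcyt2 (-0.30 ± 0.06, SE), Sipa1 (-0.64 ± 0.14), S100pbp, Bin1, Sorl1 (-0.44 ± 0.10), Hnrnpc, Stk10, Anxa2, Arhgap4 and Fasn (-0.27 ± 0.07). On the higher side they were Efcab2, Rpl23a-ps7, Get4, Ptrhd1, Cstpp1, Dhrs7, Rbm3 (0.42 ± 0.12), Rab3d, Txndc15 and Tpt1l2. All had an adjusted p of 0.994.

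Averaged over the sexes, limma called 0 features (smallest adjusted p 0.197), and 0 with the slides as a block. An unadjusted p under 0.05 was reached by 1507 features, 1003 of them lower in CR and 504 higher. Lowest by p were Fcho1 (-0.42 ± 0.07, SE) and Fgd2 (-0.60 ± 0.11), both with an adjusted p of 0.197, then Havcr1 (-0.21 ± 0.04, 0.236), Gga2 (-0.63 ± 0.12, 0.236), Hip1r (-0.40 ± 0.08, 0.372) and Scamp4 (-0.20 ± 0.05, 0.494). Higher in CR were Dse (0.32 ± 0.08), Mier1, Stfa2 (0.61 ± 0.17), Fntb, Thap12 and Tox, with adjusted p of 0.585 to 0.586. Fcho1 and Fgd2 passed the threshold with array quality weights (adjusted p 0.024 and 0.018). Without CR male replicate 2 the called genes were Fgd2, Hip1r and Gga2, and without CR female replicate 1 Fcho1.

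Across the 20581 features the male and female diet effects had a Pearson's r of 0.097 and a Spearman's rho of 0.051, and 51.6% of features had the same sign. The r was 0.036 with the slides as a block, 0.247 with array quality weights and 0.393 with scale normalization. It was -0.047 without CR female replicate 5 and 0.193 without CR male replicate 2. Features are not independent replicates. An unadjusted p under 0.05 in both sexes was reached by 77 features, where 68.3 are expected from independent lists of these sizes. Of the 77, 70 went the same way: 65 were lower in CR in both sexes and 5 higher. Male and female CR pups may share dams, so the effects in the sexes need not be independent. The labels do not tie pups to litters, so this was not tested.

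**Figure D1:**
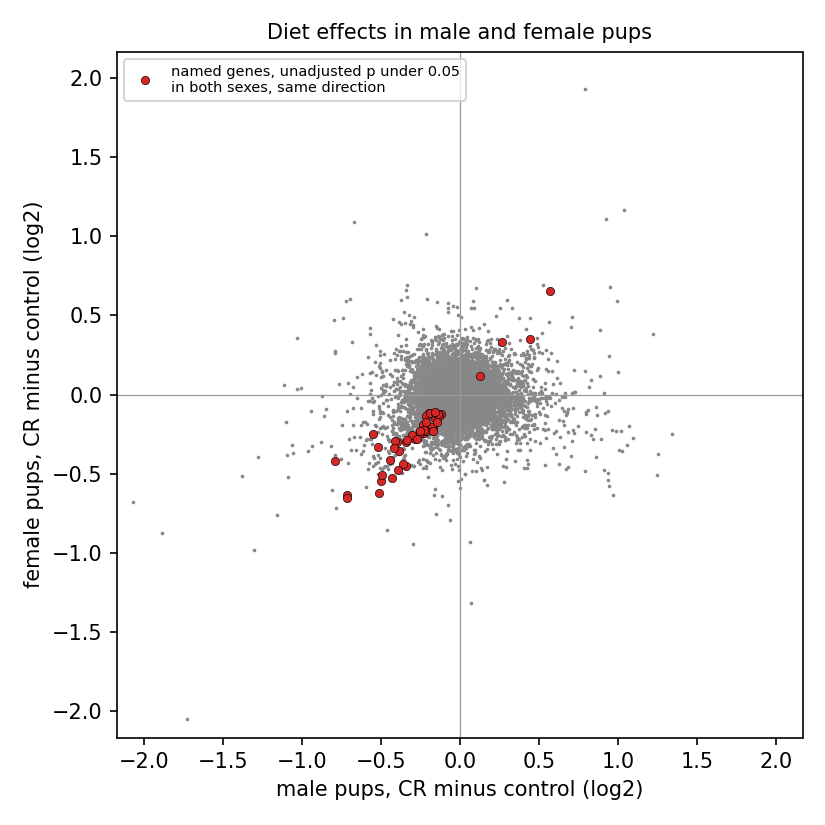
Difference between pups of CR and control dams (log2) in males on the x axis and females on the y axis, 1 point per feature. Pearson's r over the features is 0.097, and the coloured points are named genes at an unadjusted p under 0.05 in both sexes and in the same direction, most of them lower in CR.

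For the difference of the male and female effects limma called 0 features (smallest adjusted p 0.931, 960 at an unadjusted p under 0.05), and 0 with the slides as a block. The effect in males lay furthest above that in females, by p, for Rreb1 (0.36 ± 0.07, SE), Emp3 (0.43 ± 0.11), Mtmr6, Skic3 and Rab5b. It lay furthest below for Anapc7 (-0.63 ± 0.14), 2610318N02Rikl, Arhgef25, Bloc1s2 and Tmed9. Their adjusted p was 0.931 to 0.938.

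Genes of lipid metabolism were given whatever their p, and none passed the adjusted threshold in either sex. Fasn was at -0.08 ± 0.07 (CR minus control, SE) in males and -0.27 ± 0.07 in females. Srebf1 was at -0.14 ± 0.09 and -0.21 ± 0.09, Rxrb at -0.34 ± 0.11 and -0.19 ± 0.11, and Cpt1a at 0.37 ± 0.12 and 0.10 ± 0.11. The slide-blocked values in males were -0.07, -0.15, -0.31 and 0.36 in this order. Lrp1 was at 0.05 ± 0.13 in males, with a sign that depended on the probe, the normalization and 1 array (-0.07 without CR male replicate 2), and at -0.26 ± 0.12 in females. Lipe was at 0.08 ± 0.06 and 0.11 ± 0.06, and in females its probes went both ways. In males Lipe was negative when Cy5 alone was used. Star was at -0.02 ± 0.06, positive with the slides as a block and with the covariates for B cell and red cell markers, and at 0.04 ± 0.05 in females. Cd36 was at 0.96 ± 0.41 and -0.22 ± 0.39, and Ucp2 at 0.13 ± 0.24 and -0.24 ± 0.23. Without CR female replicate 5 the female values were -0.56 for Cd36 and -0.52 for Ucp2. Both were positive in females under scale normalization, and Ucp2 was negative in males under median centring and with the covariates for B cell and red cell markers. In males the adjusted p of these 9 genes ran from 0.644 to 0.975 and in females from 0.994 to 0.995.

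Camera with a preset correlation called 7 of 28 gene lists in males, 12 in females, 8 for the mean of the sexes and 4 for the difference between the sexes. With an estimated correlation it called 0 in each comparison, as did fry (either direction included) and the exact permutation test of list means. Within 1 sex the exact test cannot give a p under 0.0022, or 0.061 after adjustment for a list that reaches it alone, so 0 calls there say little about any single list. The smallest adjusted p for the mean of the sexes was 0.148, 0.074 and 0.065 by these tests. With the slides as a block the preset camera called 5, 12, 7 and 8 lists.

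B cell markers had the smallest camera p in both sexes. In males the 15 markers shifted by -0.34 ± 0.14 (SE, camera adjusted p 5.0e-07, exact permutation p 0.037, n = 5 and 6), 14 of 15 were lower, and the shift within slides was negative on 3 of 4 slides. In females the shift was -0.17 ± 0.13 (camera adjusted p 0.00026, exact permutation p 0.210, n = 6 and 6), with 11 of 15 lower and a negative shift on 4 of 6 slides. Without control female replicate 6 the female shift was -0.09 ± 0.13 (adjusted p 0.013), and the difference between the sexes was then called (-0.25, 0.035), as it was without CR male replicate 3 (-0.25, 0.042). Averaged over the sexes it was -0.26 ± 0.10 (camera adjusted p 6.1e-10) and -0.28 ± 0.11 with the slides as a block. All 15 markers were lower, 10 of them at an unadjusted p under 0.05, 0 when adjusted over all features and 9 when adjusted over the list alone. The exact permutation p was 0.013, and 0.088 adjusted over the lists. Among the members with the smallest p were Ms4a1 (-0.52 ± 0.13), Blk (-0.37 ± 0.11) and Cd22 (-0.27 ± 0.08). In males these were Blk, Cd72, Ms4a1 and Cd79b, and in females they included Ms4a1, Cd22 and Cr2. Within groups the list moved against T cell markers (r of -0.71). With their mean as a covariate its shift was -0.21 ± 0.11 in males, -0.22 in females and -0.22 for the mean of the sexes.

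The list of dendritic cell and class II genes (10 genes) shifted by -0.39 ± 0.19 in males, -0.37 ± 0.19 in females and -0.38 ± 0.13 averaged over the sexes (camera adjusted p 0.0189, 0.0065 and 0.00090). For the mean of the sexes 6 of 10 were lower, and 5 passed when adjusted over the list alone. With the slides as a block the mean shift was -0.35 ± 0.15, and the list was no longer called in males (adjusted p 0.151, over 15 settings 0.0026 to 0.292). Nor was it called in males under median centring or scale normalization, without control male replicate 1 (0.056) or 4 (0.15), or without CR male replicate 4 (0.086) or 5 (0.237). The median over the 10 genes was -0.32 in males, -0.18 in females and -0.25 for the mean. This list followed the B cell markers most closely of 6 cell types, and with their mean as a covariate its shift was -0.15 ± 0.20 in males, -0.25 ± 0.17 in females and -0.20 ± 0.14 for the mean. RT1-Db1 (-0.50 ± 0.12), Cd74 (-0.57 ± 0.16), RT1-Da and RT1-Ba had the smallest p, and they were also the first 4 in males, where Cd74 was positive with the B cell and red cell list means as covariates. RT1-Bb, the fourth by p in females, was at -2.05 ± 1.15 and drew the female list mean below the median.

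Fatty acid synthesis and desaturation shifted by -0.09 ± 0.03 for the mean of the sexes (16 genes, 12 lower, camera adjusted p 0.00090, exact permutation p 0.0023 with 0.065 after adjustment) and by the same amount with the slides as a block (-0.09 ± 0.03). It was called in females (-0.10 ± 0.04, 15 of 16 lower, 5 of 6 slides negative) and not in males (-0.08 ± 0.04, adjusted p 0.067, 4 of 4 slides negative), where it was called with the scanner software's ratio (0.012, over 15 settings 0.012 to 0.155) and without control male replicate 5 (0.043) or 6 (0.032), and the difference between the sexes was not called (0.02 ± 0.05, adjusted p 0.502). Fasn (-0.17 ± 0.05), Scd2 (-0.25 ± 0.09), Srebf1 (-0.18 ± 0.06) and Scd (-0.19 ± 0.07) had the smallest p, and 1 of the 16 passed over the list alone. Cholesterol synthesis and uptake shifted by -0.06 ± 0.02 (21 genes, 18 lower, camera adjusted p 0.010, exact permutation p 0.0054, with the slides as a block -0.07 ± 0.02), with Tm7sf2, Fdps, Cyp51 and Fdft1 first by p. Lipid transport, lipoproteins and sterol receptors shifted by -0.08 ± 0.04 (28 genes, 20 lower, adjusted p 0.0098, with the slides as a block -0.07 ± 0.04), with Rxrb (-0.26 ± 0.08), Abcg1, Apoa1 and Rxra first. Over the list alone 0 members of either list passed. In females these lists were called too, with Srebf2, Tm7sf2, Cyp51 and Fdps first in the former and Lrp1, Rxrb, Apoc1 and Nr1h2 in the latter. In males they were not (both adjusted p 0.284). For the mean of the sexes the cholesterol list was not called with the scanner software's ratio, Cy5 alone or the deposited value table (over 14 settings 0.0027 to 0.135). The lipid transport list was not called for the mean under median centring (0.221), in females under scale normalization (0.063), or without control female replicate 3 (0.088 for the mean and 0.111 in females). Its female shift without that array was -0.07 ± 0.04. Each called list was also fitted with the marker mean of each of 6 cell types, other than the list itself, in turn as a covariate. Within groups, fatty acid synthesis correlated most strongly with T cells (r of -0.55), cholesterol with B cells (0.50) and lipid transport with monocytes (0.60). With this covariate the shifts for the mean of the sexes were -0.08 ± 0.02, -0.03 ± 0.02 and -0.07 ± 0.03 in this order. In females, where monocyte markers were themselves lower, the lipid transport shift went from -0.10 ± 0.05 to -0.06 ± 0.04 with the monocyte covariate.

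**Figure D2:**
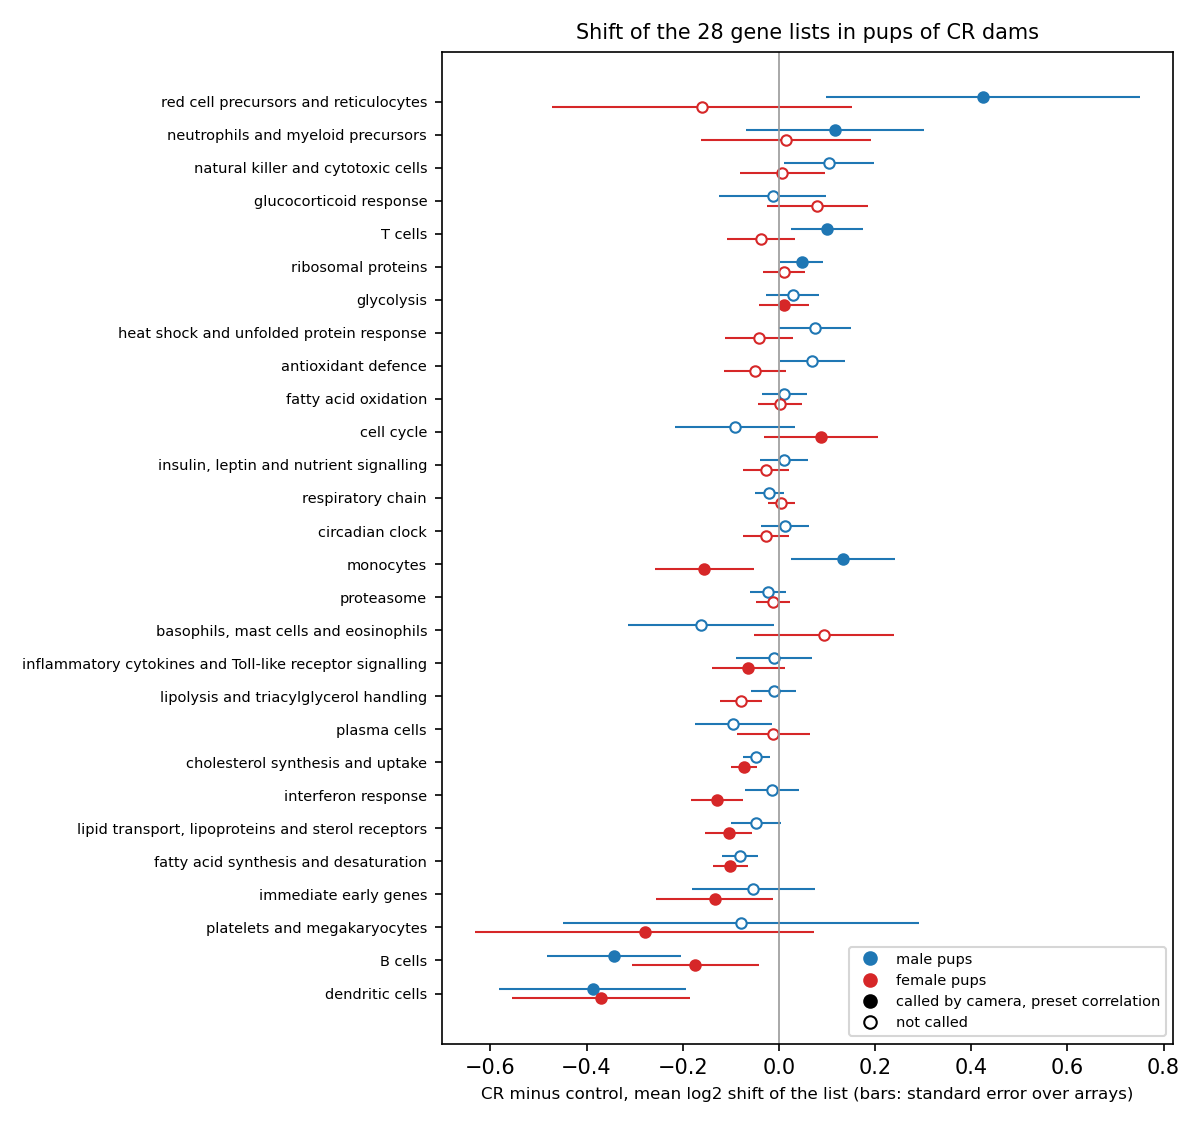
Difference of the group means of each list's per-array mean (CR minus control, log2, x axis) for the 28 lists, with standard errors over arrays. Filled points were called by camera with a preset correlation, and 0 lists were called with an estimated correlation.

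The interferon response list was called for the mean of the sexes (-0.07 ± 0.04, 36 genes, 26 lower, adjusted p 0.0098, with the slides as a block -0.08 ± 0.04) and in females (-0.13 ± 0.05, adjusted p 0.00030). Tap2 (-0.68 ± 0.20), Bst2, Stat2 and Ifitm1 were first by p for the mean, and Tap2, Zbp1, Parp14 and Stat2 in females. With the monocyte marker mean as a covariate the female shift was -0.08 ± 0.05. The list was not called under scale normalization (0.129 for the mean and 0.054 in females), and for the mean not with array quality weights or without CR male replicate 3 (0.059). Ribosomal protein genes were higher by 0.03 ± 0.03 for the mean (50 genes, 39 higher, adjusted p 0.0050) and 0.05 ± 0.04 in males (41 higher, 0.0021). Rplp2, Rps19, Rpl24 and Rplp1 were first by p for the mean, and Rps19, Rpl23, Rps16 and Rps9 in males. Median centring moved the median of all features by -0.19 in males and -0.10 for the mean, and relative to it these genes were negative, except Rplp2. Rpl24, Rplp1 and Rps16 were also negative when Cy5 alone was used. Under median centring the list was still called in males and for the mean, with a direction that was not recorded. The list was called neither in males nor for the mean with the scanner software's ratio, Cy5 alone or the deposited value table, or without CR male replicate 4 (adjusted p 0.479 in males and 0.259 for the mean, with shifts of 0.013 and 0.012). In males it was not called without control male replicate 4 (0.03, 0.095). With the red cell marker mean as a covariate the shift was 0.09 ± 0.03 in males and 0.04 ± 0.02 for the mean, and with the B cell marker mean it was negative, -0.00025 ± 0.05 and -0.0070 ± 0.03.

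Red cell markers were called higher for the mean of the sexes at an adjusted p of 0.0498 (0.13 ± 0.23, 44 genes), a call made under 5 of 14 other settings (adjusted p 0.010 to 0.972) and without 12 of the 23 arrays in turn. The shift was 0.00080 ± 0.23 with the slides as a block and -0.0080 ± 0.18 without CR female replicate 5 (adjusted p 0.896). In males the shift was 0.42 ± 0.33 (38 of 44 higher, adjusted p 5.8e-06) and 0.16 ± 0.34 with the slides as a block, where the list was not called (0.222), nor was it under scale normalization (0.133). In females it was -0.16 ± 0.31 (not called, 0.089). It was -0.44 ± 0.25 and called without CR female replicate 5 (2.5e-10), and -0.0083 ± 0.31 without control female replicate 4. The list was also called without control female replicate 1 (shift -0.31), 3 (-0.20) or 5 (-0.22). Further calls came with array quality weights, under median centring and with the 2 arrays that stand apart left out (8.6e-11). For these settings the direction was not recorded. With all arrays kept, the standard errors of the mean and female shifts exceeded the shifts. Epb41, Ank1, Cpox (lower) and Alas2 were first by p in males and Epb41, Uros, Hbb-b1 and Hbe1 for the mean.

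**Figure D3:**
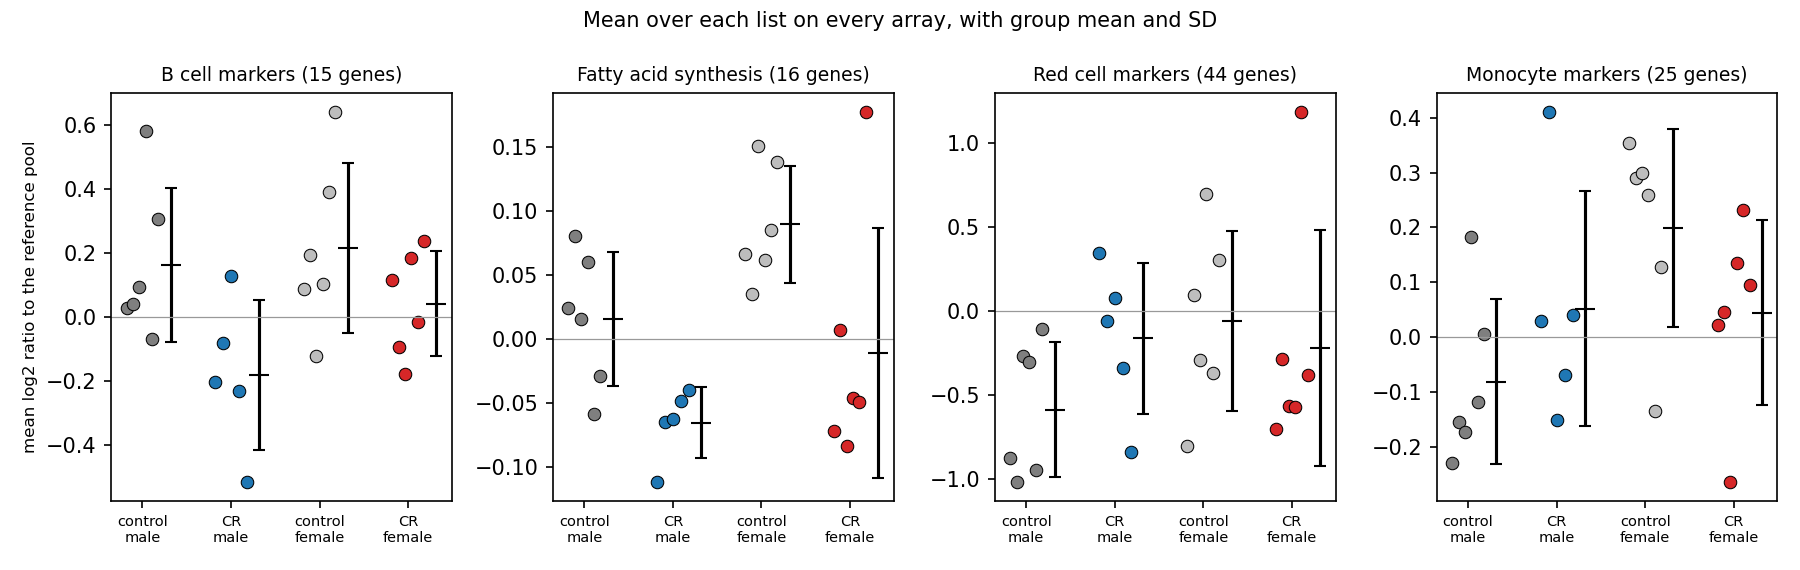
Mean log2 ratio to the reference pool (y axis) over the genes of 4 lists, 1 point per array, with each group's mean and SD beside the points. B cell markers averaged lower in CR pups of both sexes, and the red cell means of CR females ran up to 1.19.

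Further lists were called in single sexes, monocytes in both and in opposite directions. In males these were T cells (0.10 ± 0.07, adjusted p 0.0090, Cd3d, Tcf7, Il7r and Icos first), monocytes (0.13 ± 0.11, 0.015, with Cd36 and Fcgr3a higher, Ly86 lower and Mpeg1 higher) and neutrophils and myeloid precursors (0.12 ± 0.19, 0.041, Padi4, S100a9, Anxa1 and S100a8 first). The T cell list moved against the B cell markers, and with their mean as a covariate its shift in males was -0.03 ± 0.06. With the monocyte mean as a covariate the neutrophil shift was 0.01. Among 15 other settings the T cell list was called under 13, the monocyte list under 11 and the neutrophil list under 9, the slides as a block not among these (0.122). Without CR male replicate 2 none of these lists was called (0.089, 0.519 and 0.366), and the monocyte shift was 0.04. The T cell list was not called without control male replicate 4 (0.163), the monocyte list not without control male replicate 1 (0.096), and the neutrophil list was called without 16 of 23 arrays in turn. The T cell shift was 0.06 without control male replicate 4, and the neutrophil shift 0.05 without control male replicate 1. Cd3d was negative under median centring, also relative to the median of all features, where Icos and Anxa1 were positive. In females monocytes were lower (-0.16 ± 0.10, adjusted p 0.00026, Csf1r, Ctss, Mpeg1 and Lyz2 first), as were inflammatory cytokines and Toll-like receptor signalling (-0.06 ± 0.08, 0.013, Myd88, Nfkb2, Rela and Casp1), platelets and megakaryocytes (-0.28 ± 0.35, 0.021, Tbxas1, Pf4, Nrgn and Treml1) and immediate early genes (-0.13 ± 0.12, 0.048, Klf2 at -0.33 ± 0.10, Ier2 at -0.86 ± 0.30, Egr2 and Nr4a1). Egr2 was higher, and lower with the scanner software's ratio and with Cy5 alone. Cell cycle genes were higher (0.09 ± 0.12, 0.015, Kif11, Ccnb1 and Cenpf higher and Mcm7 lower). Glycolysis was called lower (0.0040) while its mean shift was 0.01 ± 0.05 and its median -0.09. With the B cell marker mean as a covariate the mean shift was -0.02 ± 0.05. The call was not made under median centring, scale normalization or Cy5 alone (over 15 settings 0.0015 to 0.515). Pgam1, Eno1 and Pfkm were lower, and Ldhb was at 1.93 ± 0.74. In females the immediate early list was called under 9 of 15 settings and without 11 of 23 arrays in turn, the platelet list under 14 and without 16, cell cycle under 10 and without 18, and the inflammatory list under 13 and without 19. Without CR female replicate 4 the shifts were -0.06 for immediate early genes (0.596) and -0.08 for platelets (0.508), without CR female replicate 6 it was 0.03 for cell cycle (0.251), and without CR female replicate 3 it was -0.03 for the inflammatory list (0.102). Over the 6 cell type covariates the shift ran from -0.10 (B cells) to -0.03 (platelets) for the inflammatory list, from -0.21 (B cells) to -0.08 (platelets) for immediate early genes and from 0.05 (T cells) to 0.19 (B cells) for cell cycle. In males the platelet list had a mean shift of -0.08 ± 0.37 and a test direction of higher (0.987).

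The difference of the male and female effects was called for red cell markers (0.58 ± 0.45, adjusted p 2.3e-06, exact permutation p 0.197), monocytes (0.29 ± 0.15, 2.3e-06, exact permutation p 0.061), cell cycle (-0.18 ± 0.17, 0.0014, exact permutation p 0.304) and T cells (0.14 ± 0.10, 0.0028, exact permutation p 0.181). With the slides as a block these shifts were 0.32 ± 0.46, 0.30 ± 0.17, -0.23 ± 0.17 and 0.16 ± 0.10. First by p were Ank1, Epb41, Sptb and Rhd among red cell genes, Mpeg1, Clec4a1, Fcgr3a and Cd36 among monocyte genes, Mcm7 (positive), E2f1, Birc5 and Ccnb1 among cell cycle genes, and Cd3d, Tcf7, Il7r and Cd3g among T cell genes. Cd3d and Cd3g were negative under median centring, also relative to the median of all features. Red cell markers were not called under scale normalization (0.823), cell cycle not under median centring or with array quality weights and T cells not under median centring or scale normalization. With the B cell marker mean as a covariate the T cell difference was 0.07 ± 0.08, and with the monocyte mean the red cell difference was 0.34. Cell cycle was not called without CR male replicate 5 (-0.13, 0.097) or control male replicate 6 (-0.10, 0.077), and T cells not without control male replicate 4 (0.10, 0.070) or CR female replicate 6 (0.08, 0.15). The cell cycle difference ran from -0.28 (red cells) to -0.05 (T cells) over the 6 cell type covariates.

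With all arrays and the processing described, the 12 remaining lists were called in no comparison. For the mean of the sexes their shifts were 0.0066 ± 0.03 for fatty acid oxidation, -0.04 ± 0.03 for lipolysis and triacylglycerol handling, -0.0074 ± 0.02 for the respiratory chain, -0.0073 ± 0.03 for insulin, leptin and nutrient signalling and -0.02 ± 0.03 for the proteasome. They were 0.02 ± 0.05 for heat shock and unfolded protein response, 0.03 ± 0.08 for glucocorticoid response, -0.0078 ± 0.03 for the circadian clock and 0.0099 ± 0.05 for antioxidant defence. Plasma cells shifted by -0.05 ± 0.05, natural killer and cytotoxic cells by 0.06 ± 0.06, and basophils, mast cells and eosinophils by -0.03 ± 0.11. Adjusted p ran from 0.146 to 0.981. The mean and the median of the fatty acid oxidation, respiratory chain and heat shock lists differed in sign. Other settings made some calls. Under median centring the respiratory chain was called in males (4.3e-08), for the mean (5.9e-05) and for the interaction (1.6e-08), and so was the proteasome (2.0e-06, 8.4e-05 and 1.1e-05). Natural killer cells were called in males with the scanner software's ratio (0.017) and with the filter on all arrays (0.0040), and in the interaction with the latter. Heat shock was called in females under 5 settings and in the interaction under 2, antioxidant defence in the interaction under 3 and in females with the 2 arrays that stand apart left out, and lipolysis in females under 2 and for the mean with array quality weights. With 1 array left out there were calls for natural killer cells, heat shock, antioxidant defence, the glucocorticoid response (in females without control female replicate 3) and basophils (in males and the interaction without CR male replicate 3).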

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

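Of the tests in this part, the counts over other splits, the bounds set for shifts with the slides as a block (a setting itself planned), those that count list members, those with T cell or platelet markers as a covariate and those of the list means by exact permutation were chosen only after the results were seen. The B cell list mean as a covariate was also chosen after the data were seen. In each group of 4 to 6 arrays, the highest or lowest array was tested by Dixon's ratio of its gap to the group's range. By chance about 1 in 20 groups meets this criterion. It was met by 5 of 112 groups for the list means, where 5.6 are expected, and by 32 of 508 for the named genes, where 25.4 are expected.

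Among the list means (log2 ratio to the pool), CR female replicate 6 stood highest in its group for fatty acid synthesis (0.18), CR male replicate 2 for lipid transport (0.054), CR male replicate 1 for natural killer cells (0.16) and CR female replicate 5 for red cell markers (1.19). Control male replicate 6 was lowest for dendritic cells (-0.48).

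CR female replicate 5 accounted for 7 of the 32 genes. It was highest in its group for Epb41 (1.12), Cd36 (1.49), Ucp2 (1.81), Hbb-b1 (2.81), Sptb (1.34) and Rhd (2.17), and lowest for Pbdc1 (-0.38). Among the other CR females, replicate 6 was apart for Nr1h2 (0.62) and Birc5 (1.098), replicate 3 for Ms4a1 (-0.75) and Tbxas1 (-0.48), replicate 1 for Sorl1 (0.30), replicate 2 for Ldhb (1.30) and replicate 4 for Fdft1 (0.32). Among the CR males, replicate 2 was apart for Ly86 (0.073), Lrp1 (0.56) and Mier1 (-0.11), replicate 4 for Rreb1 (0.044) and replicate 3 for Fasn (0.12). Among the control females, replicate 6 was apart for Fcho1 (0.82), Thap12 (-0.82) and Acy1 (0.52), replicate 3 for Fntb (-0.67) and Rplp1 (0.28), replicate 4 for Sipa1 (0.38), replicate 2 for Mcm7 (-0.35), replicate 5 for RT1-Bb (1.93) and replicate 1 for Rplp2 (-0.055). Among the control males, replicate 2 was apart for Rps19 (0.17) and Pbdc1 (-0.74), replicate 4 for Cd74 (0.80) and replicate 6 for Mpeg1 (0.17).

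The diet effect differed between the sexes, by camera with a preset correlation, for red cell markers (male minus female effect 0.58), monocytes (0.29), cell cycle (-0.18) and T cells (0.14). With an estimated correlation, fry or the exact permutation of the list means 0 of these were called. As many as 4 lists were called in 80 of 100 splits of diet within sex, the real one included, with up to 13 in another split, so chance is not excluded.

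Chance is not excluded for the other counts of lists either. The 7 lists in males were matched or exceeded in 39 of 100 splits (highest other 16), the 12 in females in 6 (highest other 15) and the 8 for the mean of the sexes in 38 (highest other 15). The median over the other splits was 6 lists in males, 7 in females, 7 for the mean of the sexes and 6 for the interaction. A count of 0 called genes is met by any split, here by 100 of 100, so this says nothing about chance in the diet comparisons. The highest count in another split was 2 in males, 5 in females, 78 for the mean of the sexes and 1 for the interaction. Genes at an unadjusted p under 0.05 were as many in 33 splits in males (1472, highest other 3585), 41 in females (955, highest other 2738), 16 for the mean (1507, highest other 2833), 55 for the interaction (960, highest other 2886) and 15 between the sexes (1524, highest other 3023). The r of 0.097 between the sexes' effects was reached in 28 splits (highest other 0.472), and the 65 features lower in both sexes in 5 (highest other 195). The 12 features called between the sexes were reached in 3 of 100 splits, the real one included. Another split called 214, so the count alone cannot exclude chance. The level of the top feature lay on the side of the labelled sex on 23 of 23 arrays. In a split of diet 78 were called, and what sets such splits apart was not tested.

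B cell markers were lower in pups of CR dams (list mean -0.26 averaged over the sexes). The tests argue against the slide as the whole cause, since the shift with the slides as a block was -0.28 ± 0.11 (SE), and against the dye or array normalization, since under 4 other ways to normalize, relative to the median of all features, the smallest shift was -0.30 ± 0.11. Single arrays stay open: without control female replicate 6 the shift was -0.22 ± 0.09, whose error reaches just below 50% of the shift with all arrays. All 15 of 15 markers were lower, which a smaller share of B cells among the cells may explain. No marker of this list is in another list. A change in the markers' expression per cell, the diet of the dam and the sharing of dams by CR pups were not tested apart from this and stay open. Chance also stays open, as the exact permutation p was 0.088 after adjustment.

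The fatty acid synthesis list was lower in pups of CR dams (list mean -0.091). The shift was -0.091 ± 0.027 (SE) with the slides as a block, and the smallest was -0.089 ± 0.022 over 4 other ways to normalize and -0.084 ± 0.026 with 1 array left out (CR female replicate 3). These values argue against the slide, the normalization and single arrays as the whole cause. Within groups the list correlated most strongly, of 6 cell types, with T cell markers (r of -0.55, against them) and platelet markers (0.47). With the mean of either as a covariate the shift was -0.082 (± 0.023 for T cells, ± 0.024 for platelets). These covariates could not have moved it far, since neither marker mean differed much between diets, averaged over the sexes, relative to its spread. T cell means were 0.07 in control and 0.17 in CR males, and 0.10 and 0.06 in females. Platelet means were -0.15 and -0.23 in males, and 0.17 and -0.11 in females. This test therefore cannot decide on the level of either set of markers. With the B cell list mean as a covariate the shift was -0.075 ± 0.031, and whether it follows the level of the B cell markers cannot be told apart, because the error reaches below 50% of the shift. The diet of the dam was not tested apart from the sharing of dams and stays open, as does chance (exact permutation p of 0.065 after adjustment).

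The diet effect on the red cell list lay higher in males than in females (difference 0.58), while in females alone the list was not called. The dye or array normalization stays open: under scale normalization the difference was 0.17 ± 0.80 (SE), under 50% of the value with loess alone but with an error that spans both. It was 0.82 ± 0.64 with the scanner software's ratio, 0.52 ± 0.50 under median centring and 0.54 ± 0.47 with Cy5 alone. The slide and single arrays cannot be told apart from the diet by sex difference, because the errors are as large as the shifts: 0.32 ± 0.46 with the slides as a block and 0.43 ± 0.44 without control female replicate 4. Without CR female replicate 5 it was 0.86 ± 0.36. Red cells carried over into the density gradient preparation, which removes most of them, are a candidate source. This predicts that nearly all members move together, and 38 of 44 had a male effect above their female effect, between the bounds set for and against it. On CR female replicate 5, Hbb-b1 was at 2.81 and the list mean at 1.19. A biological effect of the dam's diet on red cell precursors stays open and untested.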

How the results depend on the processing

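Leaving out 2 arrays together, the exact permutation of list means and the covariates for cell type markers were tests chosen only after the results were seen, as were the 214 pairs of a named gene and a comparison followed here, from which the members of lists not called were left out after some of their signs had been seen to change. All other settings were chosen before the data were examined. Single-sex fits apply to the male and female comparisons alone and were not run for the others, whose fits use all groups.

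The count of called genes was 0 in every diet comparison under every setting that kept all arrays or left out 2, with these exceptions. Array quality weights gave 2 for the mean of the sexes (Fcho1 and Fgd2), and the replicate block, which takes the replicate number as paired, gave 1 in males (Gga2). Whether the numbers pair the pups is not settled. Deviations from the group means correlated by 0.063 on average over 33 same-number pairs and by -0.011 over pairs of other numbers. The same-number values ran from -0.42 to 0.46, and 5 of 23 arrays correlated best with their own number. The cause of these exceptions was not tested. Between the sexes 6 features were called with the filter on all arrays (15691 tested), all among the 12. This filter removes those of the 12 that are not above background on every array. Examples are A_44_P324932 (above background on 1 of 11 male arrays) and A_44_P638995 (0 of 12 female arrays). Genes at an unadjusted p under 0.05 ranged from 956 to 3716 for the mean, 681 to 2458 for the interaction and 814 to 2404 between the sexes. Ms4a6bl1 was not called in 7 settings, Pbdc1 in 8 and Eif2s3 in 2.

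For lists, camera with an estimated correlation, fry and the exact permutation each called 0 in males, females, the mean of the sexes and the interaction. The first differs from the main test by taking the correlation among list members from the data in place of 0.01. Its 0 calls therefore come from that step. For fry and the exact permutation the cause was not tested, and within 1 sex the exact test cannot call a list that stands alone. The mean of the sexes gave 5 with the scanner software's log ratio, with Cy5 alone and with the deposited value table. Males gave 3 with scale normalization and 4 with Cy5 alone, and females 6 with scale normalization (5 of them among the 12). The interaction gave 7 with median centring (2 among the 4) and 8 with the filter on all arrays, with array quality weights and with the slides as a block. The r between the sexes' effects was 0.393 with scale normalization. The cause was not tested. The B cell list was called in males, females and the mean of the sexes under each of the other preset-camera settings (15, 15 and 14) and without any single array.

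With 1 array left out, called genes ranged from 0 to 4 in males (4 without CR male replicate 2), 0 to 0 in females, 0 to 3 for the mean (3 without CR male replicate 2 and 1 without CR female replicate 1), 0 to 0 for the interaction and 10 to 12 between the sexes. Called lists ranged from 4 to 9 in males (4 without CR male replicate 2 or control male replicate 4), 8 to 16 in females, 6 to 11 for the mean and 3 to 10 for the interaction. The interaction gave 10 without CR male replicate 3, 8 without CR male replicate 2, and 7 without CR male replicate 1, control male replicate 2 or control female replicate 6. The r ranged from -0.047 (without CR female replicate 5) to 0.193 (without CR male replicate 2).

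Of 3290 values of named genes under 16 other settings, 3255 kept their sign and 35 were reversed. The cause was not tested. Every probe on its own, the intensity trend with robust moderation and single-sex fits leave a difference unchanged, so they could not reverse a sign. The first of these followed the probe used and does not show conflicts between probes of a gene. Several probes were kept for 80 pairs of a gene under the naming rule and a diet comparison, members of lists not called included. In 12 of these 80 pairs the probes went in opposite directions. Median centring moved the median of all features by -0.19 in males and -0.01 in females, and reversed in males Cd3d (-0.32), Rps19 (-0.47), Icos (-0.15), Anxa1 (-0.17), Rpl23 (-0.39), Rps16 (-0.44), Rps9 (-0.47), Ucp2 (-0.37) and Lrp1 (-0.11), for the mean Rplp2 (-0.092), Rps19 (-0.25), Rpl24 (-0.16) and Rplp1 (-0.11), in the interaction Emp3 (-0.12), Cd3d (-0.37) and Cd3g (-0.36), and between the sexes Usp9x (-0.065). Relative to the median of all features, Icos, Anxa1 and Lrp1 stay positive in males, Rplp2 for the mean (median -0.10) and Emp3 in the interaction (-0.16), as do Rps9 in the deposited value table and Usp9x under scale normalization below. Cy5 alone reversed Rps16 (-0.093), Lipe (-0.061) and Lrp1 (-0.043) in males, Egr2 (-0.042) in females, and Rpl24 (-0.0071) and Rplp1 (-0.015) for the mean. Scale normalization reversed Ucp2 (0.28) and Cd36 (0.094) in females and Usp9x (-0.0030) between the sexes. The deposited value table reversed Rps9 in males (-0.0093), the scanner software's log ratio Egr2 in females (-0.14), the slides as a block Star in males (0.016), and the mean of a gene's probes Lrp1 in males (-0.058) and Lipe in females (-0.00026). The B cell and red cell covariates reversed in males Cd79b (0.041, itself a member of the B cell list, so that this value is set by construction), Cd74 (0.0029), Ucp2 (-0.23) and Star (0.039). With the B cell marker mean as a covariate the shifts of glycolysis in females (-0.024) and of ribosomal proteins in males (-0.00025) and for the mean (-0.0070) were reversed, as was that of T cells in males (-0.029). Of 4922 values with 1 array left out, 2 changed sign. Leaving out an array of the other sex cannot change a value of the male or the female comparison. Lrp1 in males ranged from -0.071 (without CR male replicate 2) to 0.11 and Usp9x between the sexes from -0.0053 (without CR female replicate 5) to 0.078.

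Signal over background limits which genes are measured: 23693 of 41012 probes passed the filter.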

Other observations

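CR female replicate 5 had a median correlation with the other arrays of 0.066 and CR male replicate 1 of 0.158. Some genes split the arrays by wide gaps. RT1-Bb lay at or below -3.41 (log2 ratio to the pool) on 6 arrays and at or above -0.45 on 17, and Ldhb at or below -2.27 on 7 arrays and at or above 0.01 on 16. Both genes were singled out after their values were seen.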
